A study of Homo sapiens with 12 samples.

How the data were processed

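Total RNA of the cardiomyocyte cultures had been isolated with a column kit, with RNA integrity numbers of 8 to 10 per the labels' protocols, and 250 ng of each sample had gone into stranded poly(A) libraries read as paired ends of 43 nt on a NextSeq 500. The deposited values were whole-number counts of fragments per gene, not normalized, per the file headers. The header records featureCounts 1.5.2 counting fragments over exons grouped by gene, with the strand setting 0 and the GENCODE 29 annotation, while the submitters' processing notes name STAR 2.5.0b, Subread 1.6.3 and the hg38 build, so the version of featureCounts differs between the sources. Read trimming and the settings of STAR were not given in the sources used here. Because strand was not used in the counting, reads of a gene and of an overlapping antisense partner could not be told apart, although the kit marks strand. All 58721 gene identifiers and their spans matched GENCODE 29, 19410 genes were at 0 in all libraries, and coordinates are those of the table.

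The labels gave 4 groups of 3 libraries: atrial or ventricular cells with DMSO or ibrutinib. They do not say that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicate pairs differed by more than sampling noise (chi-square over degrees of freedom 1.84 to 12.9), and no pair was identical. The highest values, 12.9 and 9.38, were those of atrial ibrutinib replicate 3 against its partners.

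Counts were scaled by TMM (factors 0.868 to 1.10) and filtered with filterByExpr at its minimum count of 10, which left 18021 genes. A mean per group was fitted over all 12 libraries with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (common biological coefficient of variation 0.0554), with Benjamini-Hochberg adjustment and a threshold of 0.05. The contrasts were atrial against ventricular DMSO, ibrutinib against DMSO in each cell type, the mean of both responses and their difference. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 40 lists, and again with the correlation estimated for each list. The 41 lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, and 1 list with fewer than 3 tested genes was not tested. A further 3 lists, of squamous, thyroid and eye or pigment genes, were chosen after the data were examined.

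Named genes were chosen by rule. For each contrast they had an adjusted p under 0.05, a name other than a clone name, a mean of at least 1 CPM in the higher group and group ranges that did not overlap, which chance gives for 10% of genes with 3 libraries against 3. For the mean response the same sign in both cell types took the place of the last condition. The 8 largest positive and the 8 most negative changes were taken, or for the difference of responses the 8 smallest p, together with up to 4 members of each described list with the smallest p and 18 genes of identity, drug targets and electrophysiology for every contrast. Some genes that this rule takes are not reported here.

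A fold against a group at 0 was set against a floor of 3 counts over the group, and ratios with 1 to 3 counts carry an exact 95% conditional binomial interval. Intervals and floors cover counting error only. The alternatives were DESeq2 1.42.0, RLE size factors, library totals, no count filter, a filter at 1 CPM in 3 libraries, a block for the replicate number, a fit of only the groups needed, and each library left out in turn.

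The procedures were tested on simulated counts with 200 changed genes. For the atrial contrast (17805 genes) edgeR called 40.8%, 72.9%, 66.7% and 94% of genes changed 1.25, 1.5, 2 and 4-fold, for the ventricular contrast (17809 genes) 44%, 72%, 83.7% and 94%, for the mean (17796 genes) 40%, 70%, 89.8% and 100%, for the difference of responses (17818 genes) 16.3%, 55.1%, 75.5% and 80%, and for the DMSO contrast (17438 genes) 46.9%, 75.5%, 83.7% and 98%. Unchanged genes made up 9.46%, 6.41%, 5.13%, 3.45% and 5.66% of the calls. The list test called 0 lists, but the simulated genes were drawn independently, so it was not tested on correlated genes. Tables were prepared with Python 3.11.15 and pandas 2.3.3 and plots drawn with matplotlib 3.10.9.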

Results

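Poly(A)-selected RNA was sequenced from cardiomyocytes made from HES2, an established human embryonic stem cell line. The cells were grown as embryoid bodies and directed to a ventricular-like identity, or to an atrial-like identity by adding retinoic acid while they were cardiac mesoderm. Each cell type received 1 µM ibrutinib or the vehicle DMSO for 24 h. Ibrutinib is a covalent inhibitor of Bruton's tyrosine kinase (BTK) given against B-cell cancers, and atrial fibrillation is a known side effect of the drug. The 4 groups held 3 libraries each, 12 in all. The deposited values were gene counts, with 15597634 to 17666775 counts per library in atrial DMSO, 14723021 to 16329787 in atrial ibrutinib, 13886180 to 18784446 in ventricular DMSO and 15327738 to 18542598 in ventricular ibrutinib. Of 58721 annotated genes, 18021 had enough counts to be tested. The 10 most abundant genes of a library took 11.1% ± 0.201 (SD, n = 3) of its counts in atrial DMSO, 8.97% ± 0.400 in atrial ibrutinib, 5.20% ± 0.239 in ventricular DMSO and 5.34% ± 0.0937 in ventricular ibrutinib. Genes of the mitochondrial genome held 0.00349% to 0.0123% of the counts of a library. The first principal component of log2 CPM (counts scaled to a common library size) took 79.2% of the variance and parted the cell types, the second took 6.09%, and the 4 groups did not overlap on these axes.

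**Figure D1:**
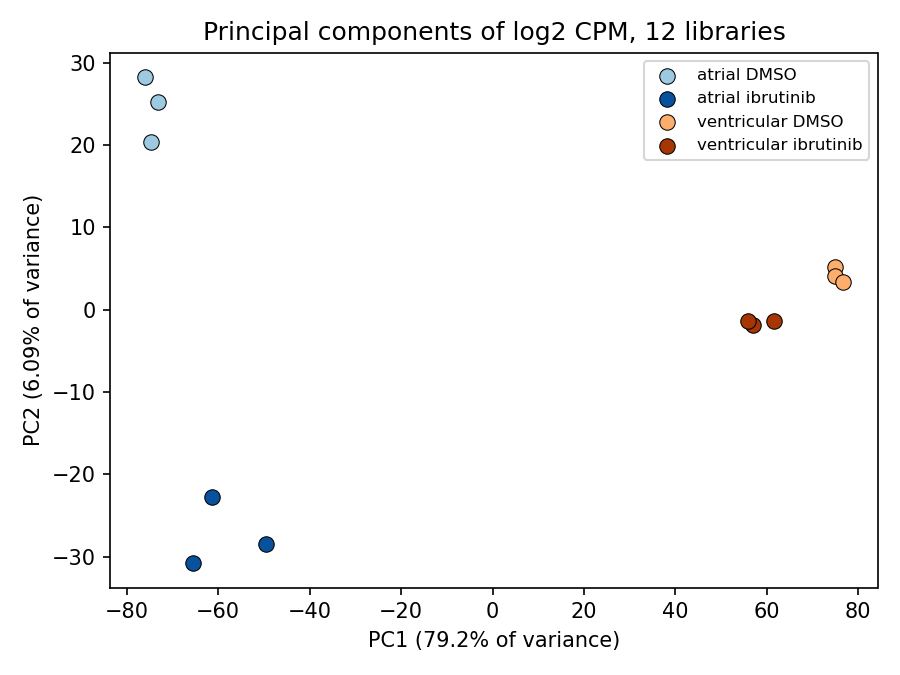
Each point is 1 of the 12 libraries, placed by its scores on the first (x axis, 79.2% of the variance) and second (y axis, 6.09%) principal components of log2 CPM, with a colour per group. Atrial DMSO libraries sit at 20.4 to 28.2 on the second component and atrial ibrutinib libraries at -30.8 to -22.7, while ventricular DMSO and ventricular ibrutinib libraries are parted along the first, at 74.8 to 76.6 and 55.9 to 61.4.

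The first comparison, atrial DMSO against ventricular DMSO, asked how far the cell types differed before any drug was given. Atrial-like cells carried far more mRNA for NPPA, which encodes atrial natriuretic peptide, at 14360 ± 782 CPM (SD, n = 3) against 79.7 ± 8.44, for the repolarising potassium channel gene KCNA5, at 271 ± 9.02 against 3.71 ± 0.761, and for the transcription factor gene NR2F2, at 409.5 ± 21.2 against 55.7 ± 2.90. Ventricular-like cells carried more MYL2, the ventricular myosin light chain gene, at 1112 ± 142 against 274 ± 24.9 CPM, and more of the ventricular transcription factor gene IRX4, at 53.2 ± 5.02 against 14.5 ± 0.733. These log2 differences, atrial over ventricular, were 7.497 ± 0.16 (SE) for NPPA, 6.19 ± 0.11 for KCNA5, 2.88 ± 0.07 for NR2F2, -2.02 ± 0.10 for MYL2 and -1.88 ± 0.08 for IRX4, with adjusted p of 3.83e-12 or lower (edgeR quasi-likelihood test). Across all genes 12777 of 18021 differed, 6161 higher and 6616 lower in atrial DMSO, of which 1477 and 3127 differed at least 2-fold.

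Other genes with large atrial excess were NPPB (brain natriuretic peptide, 6.50 ± 0.43 on the log2 scale), the sinoatrial transcription factor gene SHOX2 (6.58 ± 0.10), GHRH (6.84 ± 0.18), GSG1 (7.10 ± 0.26) and the myosin-binding protein gene MYBPHL (6.53 ± 0.23). MCEMP1 was at 0 in all 3 ventricular DMSO libraries and at least 83.3-fold higher in atrial DMSO, against a floor of 3 counts over the group. SAA1 had 400 counts in atrial DMSO and 2 in ventricular DMSO, a ratio of 250 (exact 95% counting interval 68.8 to 2070). Several of the largest ventricular excesses were in genes of the eye field, of pigment cells and of epithelia. The eye and forebrain regulator genes PAX6, ZIC1, SIX3 and RAX were at 0 in atrial DMSO and at least 229-fold, 121-fold, 79.7-fold and 57.5-fold higher in ventricular DMSO. Also at 0 in atrial DMSO were the epithelial sodium channel subunit gene SCNN1G (at least 81.2-fold), AMTN (at least 77.5-fold) and REG3A (at least 74.3-fold). The melanin synthesis gene DCT had 1454 counts in ventricular DMSO and 2 in atrial DMSO, a ratio of 581 (exact 95% counting interval 161 to 4800).

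Of 18 atrial marker genes 14 were higher and 2 lower in atrial DMSO (15 and 2 adjusted over the list alone), with a median log2 difference of 2.13, GJA5 at 4.38 and PAM at 2.66 (adjusted p = 0.142 with an estimated correlation). Of 13 ventricular marker genes 10 were lower and 3 higher (10 and 3 adjusted over the list alone). PRDM16 stood at -3.43, HEY2 at -3.36 and MASP1 at -2.27 (adjusted p = 0.218 with an estimated correlation). Of 12 nodal marker genes 9 were higher and 1 lower (9 and 1 adjusted over the list alone), among them VSNL1 at 5.36 and the pacemaker channel gene HCN4 at 2.56, while TBX3 was lower at -1.12 (adjusted p = 0.146 with an estimated correlation). Retinoic acid target genes were mostly lower in the cells that had received retinoic acid: 14 of 20 were lower and 4 higher (14 and 4 adjusted over the list alone), with CRABP2 at -2.54 and the retinoic acid-degrading enzyme gene CYP26B1 at -1.89 (adjusted p = 0.142 with an estimated correlation). Its relative CYP26A1 had 579 counts in ventricular DMSO and 2 in atrial DMSO, a ratio of 231 (exact 95% counting interval 63.7 to 1910).

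In 6 lists of sarcomere, mitochondrial, ion channel, cell cycle and sterol genes more members were higher than lower in atrial DMSO. Ventricular DMSO cultures also carried mRNA of epithelial lineages, described below. The values are thus differences between whole cultures, not between cardiomyocytes alone. All 39 nuclear genes of oxidative phosphorylation were higher (39 adjusted over the list alone), with a mean log2 difference of 1.27, CYCS at 2.41 and NDUFS1 at 1.56 (adjusted p = 0.232 with an estimated correlation). Of 27 sarcomere genes 23 were higher and 4 lower (23 and 4 adjusted over the list alone). MYL7 stood at 2.38 and the myosin chaperone gene UNC45B at 1.67 (adjusted p = 0.232 with an estimated correlation). Of 36 cardiac ion channel genes 24 were higher and 6 lower (24 and 6 adjusted over the list alone), or 19 and 13 with library totals, where the median went from 0.51 to 0.21. KCNJ3 stood at 2.19 and KCNH2 at 1.65 (adjusted p = 0.146 with an estimated correlation). Of 32 proliferation genes 29 were higher and 0 lower (30 and 0 adjusted over the list alone), or 19 and 1 with library totals, where the median went from 0.47 to 0.16. AURKA stood at 1.28 (adjusted p = 0.232 with an estimated correlation). Of 24 cholesterol synthesis genes 22 were higher and 1 lower (22 and 1 adjusted over the list alone). HMGCS1 stood at 1.39 (adjusted p = 0.232 with an estimated correlation). The 13 genes of the mitochondrial genome were all higher (13 adjusted over the list alone), from the small share of counts given above (adjusted p = 0.142 with an estimated correlation).

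Of 17 NF-kB target genes 16 were lower and 1 higher in atrial DMSO (16 and 1 adjusted over the list alone). CCL2 stood at -2.14 and TNFAIP3 at -2.27 (adjusted p = 0.146 with an estimated correlation). Of 18 interferon-stimulated genes 16 were lower and 0 higher (16 and 0 adjusted over the list alone). IFI44L stood at -4.19 and OAS3 at -3.83 (adjusted p = 0.142 with an estimated correlation). Of 24 glycolysis and hypoxia genes 20 were lower and 2 higher (20 and 2 adjusted over the list alone), with the carbonic anhydrase gene CA9 at -4.26 and KDM3A at -1.13 (adjusted p = 0.448 with an estimated correlation). Markers of other lineages were higher in ventricular DMSO too: 13 of 17 endoderm and liver genes (4 were lower there), with the intestinal regulator gene CDX2 at -3.99 (13 and 4 adjusted over the list alone, adjusted p = 0.415 with an estimated correlation), and 5 of 5 pluripotency genes, with SALL4 at -3.33 (5 adjusted over the list alone, adjusted p = 0.146 with an estimated correlation). Only these 5 of the 12 genes of the pluripotency list had enough counts to be tested. The pluripotency call was lost with a filter at 1 CPM (adjusted p = 0.069). Squamous epithelial genes, a list chosen after the data were examined, were lower in atrial DMSO in 19 of 20 cases, and KRT5 stood at 700 ± 38.3 CPM and KRT19 at 882 ± 71.7 CPM in ventricular DMSO.

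Of the remaining lists past the threshold with the preset correlation in this comparison, 6 had mostly higher genes in atrial DMSO. They were stress and natriuretic genes (11 higher and 1 lower of 12), heat shock genes (12 and 2 of 14), fatty acid oxidation (15 and 5 of 25), calcium handling (17 and 7 of 24), fatty acid synthesis (9 and 2 of 12) and smooth muscle genes (8 and 2 of 11). With an estimated correlation the adjusted p was 0.142 for stress and natriuretic genes, 0.306 for smooth muscle genes and 0.232 for each of the other 4. Immediate early genes (15 lower and 1 higher of 20), Notch and Wnt targets (13 and 2 of 16) and fibroblast matrix genes (14 and 3 of 21) were mostly lower (adjusted p = 0.448, 0.142 and 0.603 with an estimated correlation). Adjusted over the list alone 16 immediate early genes were lower, and the other counts were the same. Of the 24 lists past it, 0 stayed past it when the correlation between genes was estimated from the data (limma camera, lowest adjusted p = 0.142), where 10 had an unadjusted p under 0.05. Scaling by library totals in place of TMM shifted the median log2 difference of all genes by -0.305 and gave 3551 higher and 9741 lower genes in place of 6161 and 6616. Calcium handling then had 12 higher and 9 lower genes (median 0.13 in place of 0.43), fatty acid oxidation 13 and 7 (0.14 in place of 0.45) and fatty acid synthesis 5 and 3 (0.051 in place of 0.36). Smooth muscle genes came to 6 and 3 (0.50 in place of 0.80), while the medians of cholesterol synthesis, heat shock and fibroblast matrix genes went from 0.72, 0.87 and -0.55 to 0.41, 0.57 and -0.86.

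Among the kinases reported as ibrutinib targets, BTK itself was scarce, at 1.45 ± 0.477 CPM in atrial DMSO and 0.105 ± 0.0783 in ventricular DMSO (log2 difference 3.63 ± 0.46, adjusted p = 5.41e-08). ERBB2 stood at 486 ± 13.6 and 404.5 ± 27.9 CPM, ERBB4 at 63.2 ± 4.29 and 48.4 ± 1.54, EGFR at 53.2 ± 4.34 and 69.6 ± 3.21, CSK at 51.2 ± 2.41 and 57.9 ± 2.12 and TEC at 8.10 ± 0.708 and 7.17 ± 0.605 in atrial and ventricular DMSO. The log2 differences of ERBB2 (0.26) and ERBB4 (0.39) passed the test and EGFR was lower in atrial DMSO (-0.39), while that of TEC (0.17, adjusted p = 0.201) missed it. Scaled by library totals, ERBB2 came to -0.040 (adjusted p = 0.527) and ERBB4 to 0.08 (adjusted p = 0.262), both short of the threshold. The lower CSK level in atrial DMSO (-0.17) was not past the threshold without atrial DMSO replicate 1 (-0.15), atrial DMSO replicate 3 (-0.16) or ventricular DMSO replicate 1 (-0.15). TNNT2 (1.02), CACNA1C (0.48), RYR2 (0.88) and ATP2A2 (2.39) were higher in atrial DMSO and KCNJ2 was lower (-1.60).

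The second comparison asked what ibrutinib changed in atrial-like cells. Of 21 ERK feedback and target genes, which respond to ERK signalling, 19 fell (adjusted p = 0.1 for the list with an estimated correlation). SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, went from 32.1 ± 1.70 to 3.49 ± 0.541 CPM (SD, n = 3), and the ETS factor genes ETV4 and ETV5 went from 6.12 ± 0.800 to 0.650 ± 0.0210 and from 22.2 ± 1.19 to 2.82 ± 0.908. The natriuretic peptide gene NPPB fell from 4225 ± 544 to 388 ± 212 CPM, and BMP10, an atrial growth factor gene, from 4.75 ± 0.679 to 0.386 ± 0.126. Log2 changes were -3.21 ± 0.13 (SE) for SPRY4, -3.22 ± 0.23 for ETV4, -2.98 ± 0.14 for ETV5, -3.44 ± 0.37 for NPPB and -3.62 ± 0.31 for BMP10, with adjusted p of 0.000125 or lower. In all 5808 genes changed, 2659 higher and 3149 lower, of which 363 and 217 changed at least 2-fold.

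The other genes with the most negative changes were the immediate early factor gene EGR2 (-4.07 ± 0.38), ATP1B4 of the Na,K-ATPase beta family (-3.20 ± 0.13) and the R-type calcium channel gene CACNA1E (-3.06 ± 0.38). The largest rises were in CRABP1, a retinoic acid-binding protein gene (2.39 ± 0.25), the extracellular matrix gene ECM2 (2.17 ± 0.48), the glutamate transporter gene SLC1A2 (2.04 ± 0.21), the skeletal alpha-actinin gene ACTN3 (1.94 ± 0.27), the sodium channel gene SCN3A (1.93 ± 0.37), C1QL3 (1.86 ± 0.30), the long noncoding RNA PCAT14 (1.85 ± 0.22) and the neuroserpin gene SERPINI1 (1.84 ± 0.11). Their adjusted p values lay between 3.13e-13 and 0.000855. In hg38 coordinates SPRY4 (ENSG00000187678.9) lies on chromosome 5 from 142310427 to 142326455 on the minus strand, ETV5 (ENSG00000244405.7) on chromosome 3 from 186046308 to 186110318 on the minus strand, and NPPB (ENSG00000120937.8) on chromosome 1 from 11857464 to 11858931 on the minus strand, next to NPPA (ENSG00000175206.10) at 11845709 to 11848345. Counts were over annotated exons of these protein-coding genes.

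In 7 signal-responsive lists more genes fell than rose. Of 21 ERK feedback and target genes 19 fell and 0 rose (19 and 0 adjusted over the list alone), with a median log2 change of -1.14, EPHA2 at -1.60 and the ERK phosphatase gene DUSP6 at -2.62 (adjusted p = 0.1 with an estimated correlation). Of 20 immediate early genes 13 fell and 1 rose (14 and 1 adjusted over the list alone). DUSP1 stood at -1.13 and ATF3 at -1.43 (adjusted p = 0.226 with an estimated correlation). Of 12 stress and natriuretic genes 10 fell and 1 rose (11 and 1 adjusted over the list alone). CTGF stood at -1.97, THBS1 at -1.32 and XIRP1 at -0.83 (adjusted p = 0.1 with an estimated correlation). Of 23 YAP target genes 17 fell and 1 rose (17 and 1 adjusted over the list alone). CYR61 stood at -1.23 and AMOTL2 at -0.56 (adjusted p = 0.162 with an estimated correlation). Of 14 heat shock genes 12 fell and 0 rose (13 and 0 adjusted over the list alone). HSPH1 stood at -0.81 and HSPA8 at -0.57 (adjusted p = 0.226 with an estimated correlation). Of 22 ATF4 targets 10 fell and 1 rose (13 and 1 adjusted over the list alone). SLC7A5 stood at -0.91 and TRIB3 at -0.86 (adjusted p = 0.442 with an estimated correlation). Of 6 aryl hydrocarbon receptor targets 4 fell and 0 rose (4 and 0 adjusted over the list alone). CYP1B1 stood at -1.95 (adjusted p = 0.207 with an estimated correlation).

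The same held for 5 lists of lipid synthesis, contractile and respiratory genes. All 24 cholesterol synthesis genes fell (24 adjusted over the list alone), with a median log2 change of -0.57, among them HMGCS1 at -0.87 and NSDHL at -0.96 (adjusted p = 0.162 with an estimated correlation). Of 12 fatty acid synthesis genes 10 fell and 0 rose (10 and 0 adjusted over the list alone). FASN stood at -0.83, ACLY at -0.56 and SCD at -0.54 (adjusted p = 0.144 with an estimated correlation). Of 27 sarcomere genes 20 fell and 1 rose (21 and 2 adjusted over the list alone). SMPX stood at -0.74, UNC45B at -0.60, TPM1 at -0.62 and NEBL at -0.45 (adjusted p = 0.358 with an estimated correlation). Of 39 nuclear oxidative phosphorylation genes 20 fell and 1 rose (20 and 1 adjusted over the list alone). CYCS stood at -0.57 and ATP5MC1 at -0.49 (adjusted p = 0.729 with an estimated correlation). Of 11 smooth muscle genes 8 fell and 0 rose (8 and 1 adjusted over the list alone). MYH11 stood at -1.26 and TAGLN at -1.41 (adjusted p = 0.162 with an estimated correlation).

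Of the 16 lists past the threshold with the preset correlation, 4 had more genes that rose than fell. Of 12 nodal markers 8 rose and 1 fell (8 and 2 adjusted over the list alone). RGS6 stood at 1.00, SHOX2 at 0.42 and CACNA1G at 0.48 (adjusted p = 0.226 with an estimated correlation). Of 21 fibroblast matrix genes 11 rose and 0 fell (13 and 0 adjusted over the list alone). COL6A2 stood at 0.52, PDGFRA at 0.53 and COL3A1 at 0.60 (adjusted p = 0.666 with an estimated correlation). Of 18 interferon-stimulated genes 8 rose and 1 fell (8 and 1 adjusted over the list alone). IFIT1 stood at 1.24 and IFIH1 at 1.46 (adjusted p = 0.226 with an estimated correlation). Of 24 glycolysis and hypoxia genes 9 rose and 2 fell (10 and 2 adjusted over the list alone). PDK1 stood at 0.58 and ADM at 0.64, while the hexokinase gene HK1 fell by 0.44 (adjusted p = 0.886 with an estimated correlation). The glycolysis call was lost without atrial DMSO replicate 3 (adjusted p = 0.0872) and without atrial ibrutinib replicate 3 (adjusted p = 0.474). The median of all genes moved by 0.144 on the log2 scale when library totals replaced TMM, which gave 5170 higher and 1541 lower genes in place of 2659 and 3149. The medians of the 16 lists kept their sign. Oxidative phosphorylation came to 3 higher and 9 lower (median -0.029 in place of -0.17), fatty acid synthesis to 1 and 5 (-0.12 in place of -0.27), sarcomere genes to 3 and 13 (-0.20 in place of -0.34) and YAP targets to 2 and 10 (-0.17 in place of -0.315). Heat shock genes came to 0 and 7 (-0.18 in place of -0.32), ATF4 targets to 3 and 7 (-0.165 in place of -0.31), aryl hydrocarbon receptor targets to 0 and 4 (-0.17 in place of -0.315), smooth muscle genes to 1 and 7 (-0.28 in place of -0.43) and glycolysis and hypoxia to 14 and 2 (0.39 in place of 0.25). With an estimated correlation 0 of the 16 passed (limma camera) and 7 lists had an unadjusted p under 0.05.

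Electrical and calcium-handling genes went both ways in atrial-like cells, with list medians that changed sign with library totals, and neither list passed the test (7 of 36 ion channel genes higher and 12 lower, 8 and 12 adjusted over the list alone; 3 of 24 calcium-handling genes higher and 9 lower, 3 and 10 adjusted over the list alone). With library totals 12 ion channel genes were higher and 7 lower (median 0.059 in place of -0.084), and 6 and 6 calcium-handling genes (0.034 in place of -0.11). The potassium channel subunit gene KCNIP2 rose (0.96 ± 0.10), while KCND3 (-1.04 ± 0.13), KCNA4 (-0.90 ± 0.13), HCN2 (-0.52 ± 0.09), the calsequestrin gene CASQ2 (-0.72 ± 0.06) and JPH1 (-0.65 ± 0.06) fell. The calcium pump gene ATP2A2 fell by 0.33 and KCNJ3 by 0.29, the latter reaching only -0.14 (adjusted p = 0.104) with library totals. KCNA5 (-0.089), KCNJ2 (0.12), CACNA1C (-0.11) and RYR2 (0.16) missed the threshold, with adjusted p from 0.124 to 0.784. Of identity genes NPPA fell by 0.77, MYL2 by 0.41 and IRX4 rose by 0.52, while NR2F2 came to 0.14 (adjusted p = 0.0981). TNNT2 stood at -0.18 (adjusted p = 0.0335), a call lost without any of 5 of the 6 atrial libraries (all but ibrutinib replicate 3, -0.20 to -0.12) and with library totals (-0.037, adjusted p = 0.638). In a fit of the atrial groups alone TNNT2 came to -0.16 (adjusted p = 0.152), short of the threshold.

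Of the 14 tested kinases of the ibrutinib target list 5 rose and 0 fell in atrial-like cells (5 and 0 adjusted over the list alone), and the list itself missed the threshold (adjusted p = 0.279). ERBB3 (0.63), ERBB2 (0.24) and ERBB4 (0.24) rose. EGFR stood at 0.27 (adjusted p = 0.0285), a call lost without atrial DMSO replicates 2 or 3 or atrial ibrutinib replicates 1 or 2 (0.18 to 0.28) and in a fit of the atrial groups alone (0.30, adjusted p = 0.0685), and JAK3 at 0.48, lost without atrial DMSO replicate 3 (0.36). BTK (-0.34, adjusted p = 0.414), TEC (-0.027, adjusted p = 0.893) and CSK (-0.12, adjusted p = 0.158) missed the threshold.

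**Figure D2:**
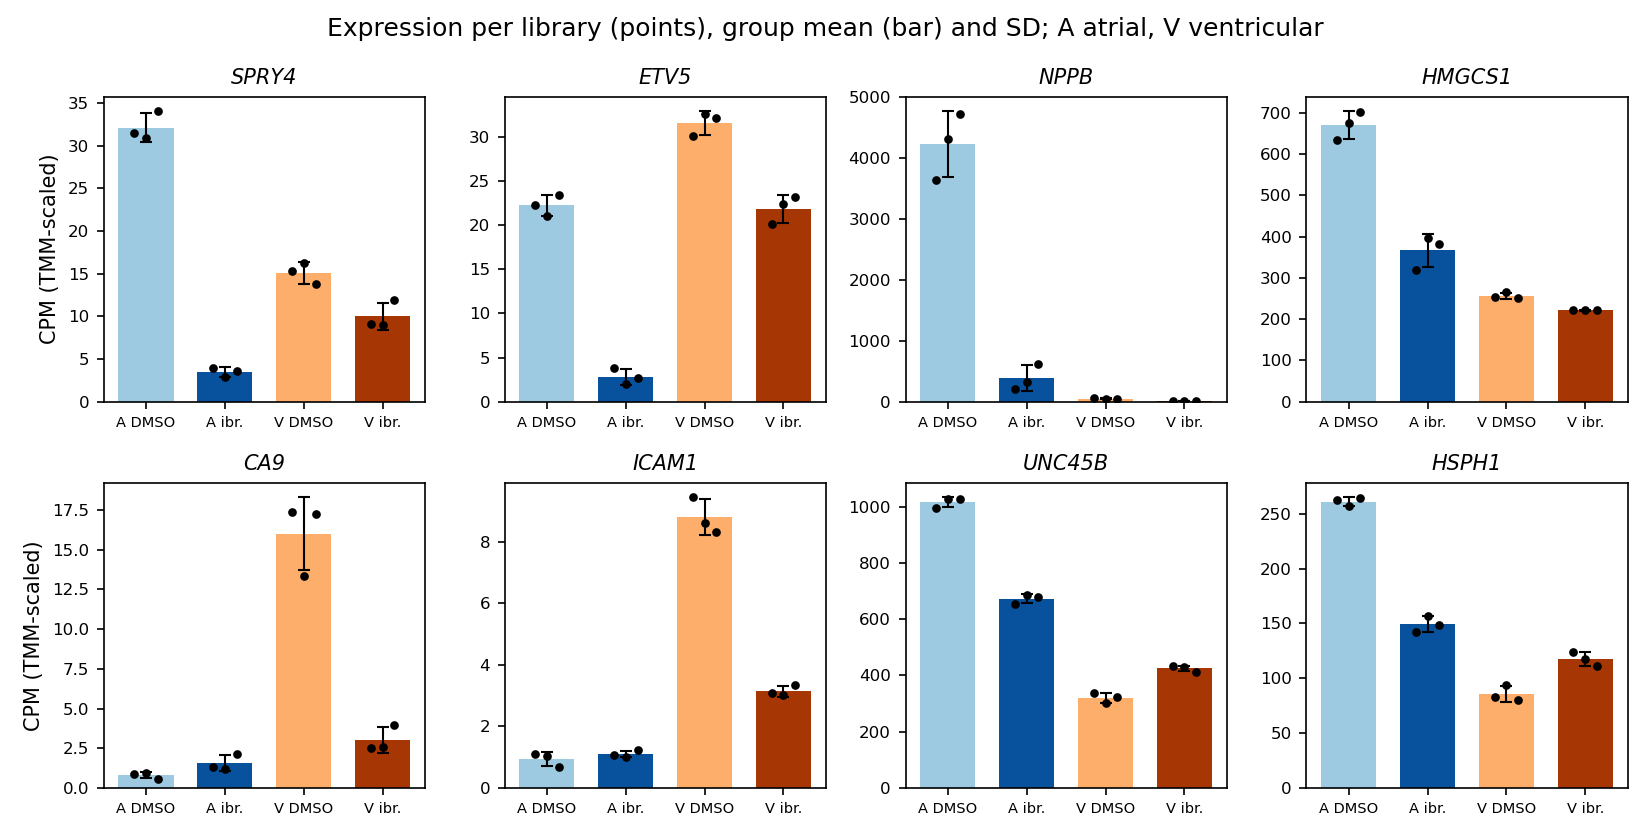
Expression of 8 genes in TMM-scaled CPM (y axis, linear, from 0), with a point per library, bars at the group mean and whiskers of 1 SD (n = 3), for atrial (A) and ventricular (V) cells with DMSO or ibrutinib (ibr.). SPRY4 drops from 32.1 to 3.49 CPM in atrial cells and from 15.1 to 9.99 in ventricular cells, CA9 is at 16 CPM in ventricular DMSO and 3.04 in ventricular ibrutinib, and UNC45B and HSPH1 fall in atrial cells and rise in ventricular cells.

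The third comparison asked the same of ventricular-like cells. All 24 glycolysis and hypoxia genes and 15 of 17 NF-kB target genes fell (adjusted p = 0.307 and 0.2 for these lists with an estimated correlation). CA9, a hypoxia-induced carbonic anhydrase gene, went from 16 ± 2.30 to 3.04 ± 0.822 CPM (SD, n = 3), the E-selectin gene SELE from 2.70 ± 0.186 to 0.546 ± 0.114, and the apelin gene APLN from 10.5 ± 1.19 to 2.46 ± 0.785. Log2 changes were -2.37 ± 0.16 (SE) for CA9, -2.29 ± 0.27 for SELE and -2.06 ± 0.20 for APLN, with adjusted p of 5.79e-07 or lower (edgeR quasi-likelihood test). In all 4612 genes changed, 1892 higher and 2720 lower, of which 50 and 305 changed at least 2-fold. The number of higher genes was 1161 without ventricular DMSO replicate 3, and 1217 and 1256 without ventricular ibrutinib replicates 1 and 2. CA9 (ENSG00000107159.12) lies on chromosome 9 from 35673856 to 35681159 on the plus strand of hg38.

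Other large falls were in the carcinoembryonic antigen gene CEACAM5 (-2.57 ± 0.29), C19orf67 (-2.40 ± 0.27), the cytochrome oxidase subunit gene COX4I2 (-2.19 ± 0.31), the lipoprotein lipase inhibitor gene ANGPTL4 (-2.03 ± 0.31) and LINGO1-AS1 (-3.21 ± 0.37). Rises were smaller: the UDP-sugar receptor gene P2RY14 (1.76 ± 0.29), the proteoglycan gene OGN (1.21 ± 0.30), ART3 (1.18 ± 0.20), LRRC4 (1.06 ± 0.11), the serotonin transporter gene SLC6A4 (1.04 ± 0.16), TONSL-AS1 (1.09 ± 0.34) and the processed pseudogenes HMGB1P1 (1.23 ± 0.19) and RPL7P3 (1.05 ± 0.18). LINGO1-AS1 and TONSL-AS1 lie antisense to LINGO1 and TONSL and the counting did not use strand, so reads of each pair could not be told apart. The pseudogenes resemble their parent genes closely, and their values are uncertain. The TONSL-AS1 call was lost with DESeq2 and without ventricular DMSO replicate 2 (0.80, adjusted p = 0.103).

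All 24 glycolysis and hypoxia genes fell (24 adjusted over the list alone), with a median log2 change of -0.79, GAPDH at -0.66, ALDOA at -0.58 and P4HA1 at -0.76 (adjusted p = 0.307 with an estimated correlation). Of 17 NF-kB target genes 15 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -0.97, the chemokine gene CCL2 at -1.12, TNFAIP2 at -1.42, ICAM1 at -1.47 and PTGS2 at -0.97 (adjusted p = 0.2 with an estimated correlation). Of 20 immediate early genes 15 fell and 0 rose (17 and 0 adjusted over the list alone). BTG2 stood at -0.72, EGR2 at -1.73 and DUSP1 at -0.78 (adjusted p = 0.307 with an estimated correlation). Of 21 ERK feedback genes 14 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.53, ETV4 at -1.13, DUSP6 at -0.75, PHLDA1 at -0.74 and MYC at -0.73 (adjusted p = 0.307 with an estimated correlation). Of 24 cholesterol synthesis genes 16 fell and 2 rose (19 and 2 adjusted over the list alone). DHCR7 stood at -0.54 (adjusted p = 0.444 with an estimated correlation). Of 12 fatty acid synthesis genes 7 fell and 1 rose (9 and 1 adjusted over the list alone). SCD stood at -0.77 and SREBF1 at -0.74 (adjusted p = 0.307 with an estimated correlation). Squamous epithelial genes, the list chosen after the data were examined, moved with these lists: 10 of 20 fell and 0 rose, with a median of -0.56.

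Other lists with more genes that fell than rose were fibroblast matrix genes (12 of 21 fell and 0 rose, 13 and 0 adjusted over the list alone), with LOX at -0.88 and COL6A2 at -0.61 (adjusted p = 0.467 with an estimated correlation), and ribosomal protein genes (17 of 34 fell and 0 rose, 19 and 0 adjusted over the list alone), with a median of -0.17 and RPL8 at -0.29 (adjusted p = 0.523 with an estimated correlation). Of 17 circadian genes 9 fell and 1 rose (10 and 2 adjusted over the list alone). BHLHE40 stood at -1.68, BHLHE41 at -1.53 and PER1 at -0.52 (adjusted p = 0.307 with an estimated correlation). Of 20 retinoic acid targets 9 fell and 0 rose (10 and 0 adjusted over the list alone). CYP26A1 stood at -0.91 and CYP26B1 at -0.87 (adjusted p = 0.2 with an estimated correlation). Of 18 interferon-stimulated genes 10 fell and 1 rose (10 and 1 adjusted over the list alone). OAS3 stood at -0.91, while IFIT1 rose by 0.50 (adjusted p = 0.435 with an estimated correlation). Of 22 ATF4 targets 9 fell and 0 rose (11 and 0 adjusted over the list alone). GDF15 stood at -0.92 (adjusted p = 0.467 with an estimated correlation). Of 11 endothelial genes 4 fell and 0 rose (4 and 0 adjusted over the list alone). EGFL7 stood at -0.95 (adjusted p = 0.348 with an estimated correlation). The endothelial call was lost without ventricular DMSO replicate 2 (adjusted p = 0.0776) and without ventricular ibrutinib replicate 3 (adjusted p = 0.0645), and with a filter at 1 CPM (adjusted p = 0.0954).

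In 3 lists past the threshold in ventricular-like cells more genes rose than fell. Of 27 sarcomere genes 14 rose and 0 fell (15 and 0 adjusted over the list alone). UNC45B stood at 0.41, LDB3 at 0.39, MYBPC3 at 0.39 and MYL7 at 0.44 (adjusted p = 0.467 with an estimated correlation). Of 32 proliferation genes 13 rose and 2 fell (16 and 4 adjusted over the list alone). KIF20A stood at 0.49, BIRC5 at 0.42 and PLK1 at 0.40 (adjusted p = 0.467 with an estimated correlation). Of 14 heat shock genes 5 rose and 0 fell (5 and 0 adjusted over the list alone). HSPH1 stood at 0.45 and DNAJA1 at 0.41 (adjusted p = 0.467 with an estimated correlation). MYL2 (0.44), IRX4 (0.49), CACNA1C (0.32), CACNB2 (0.43), KCNJ3 (0.36), KCNIP2 (0.64), SLC8A1 (0.34) and ERBB4 (0.50) rose and EGFR fell by 0.39, JAK3 by 0.79 and LYN by 0.51. NPPA (-0.013), NR2F2 (0.033), KCNJ2 (0.072), RYR2 (0.26), BTK (1.15), TEC (-0.28), CSK (0.06) and ERBB2 (0.07) missed the threshold, with adjusted p from 0.0803 to 0.959.

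A set of smaller ventricular calls rested on few libraries. TNNT2 (0.20) was not past the threshold without ventricular DMSO replicate 2 or ventricular ibrutinib replicates 1 or 2 (0.17 to 0.20), and ATP2A2 (0.18) without ventricular DMSO replicates 1 or 3 or ventricular ibrutinib replicates 1 or 2 (0.16 to 0.19). KCNA5 (-0.60) lost its call without ventricular DMSO replicate 3 (-0.41) and without ventricular ibrutinib replicates 1 (-0.59) or 2 (-0.48). With the preset correlation 16 lists passed in ventricular-like cells and 0 with an estimated correlation (limma camera), where the lowest adjusted p = 0.2 and 5 lists had an unadjusted p under 0.05.

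**Figure D3:**
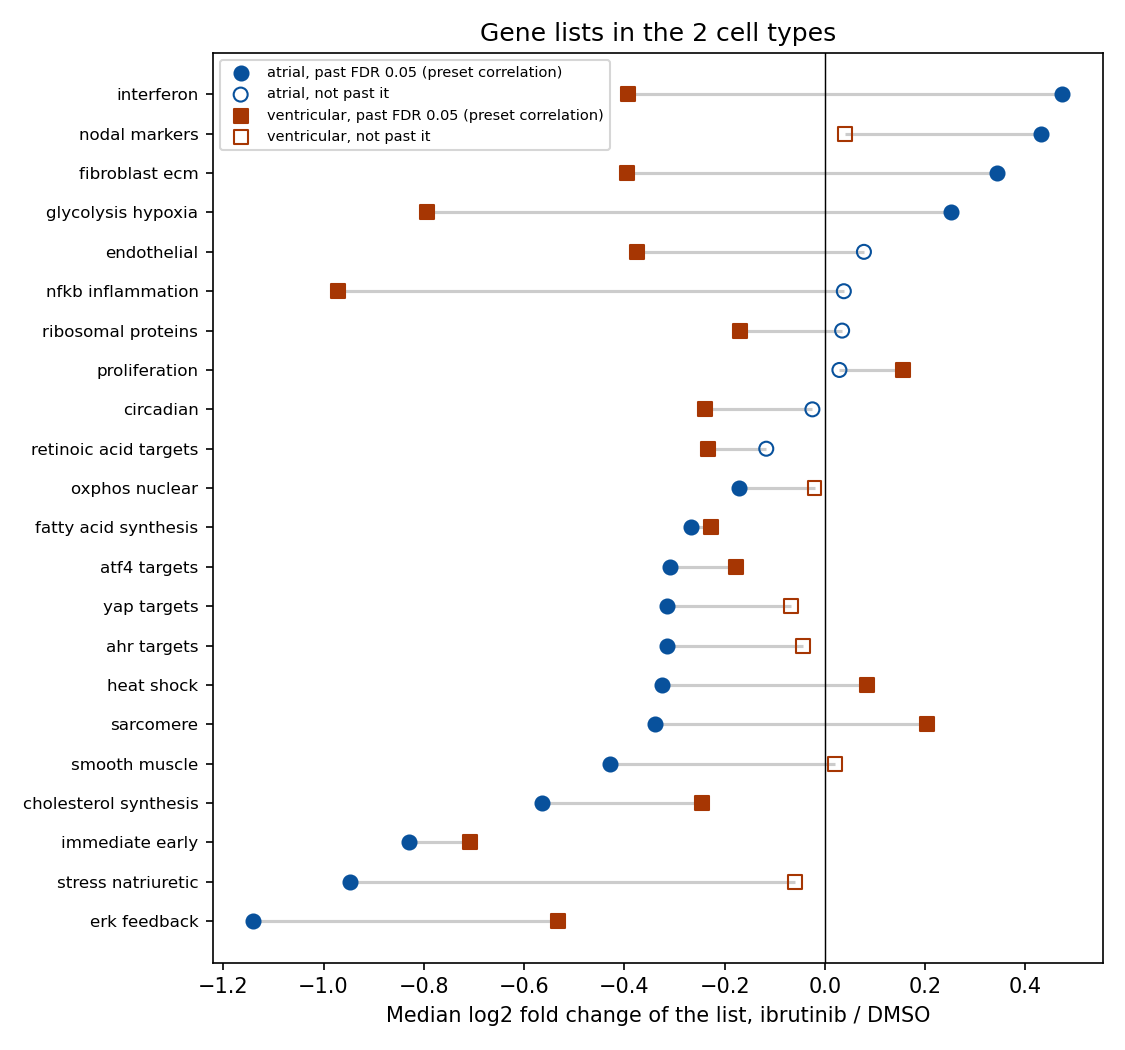
Median log2 fold change (x axis, ibrutinib over DMSO) of each gene list that passed FDR 0.05 with the preset correlation in at least 1 cell type, with circles for atrial and squares for ventricular cells, filled where the list passed in that cell type. The ERK feedback list lies at -1.14 in atrial and -0.53 in ventricular cells, the glycolysis and hypoxia list at 0.25 and -0.79, and the sarcomere list at -0.34 and 0.20, and 0 of the lists passed with an estimated correlation. With library totals the atrial medians of the glycolysis and sarcomere lists were 0.39 and -0.20, and those of the circadian and retinoic acid lists changed sign.

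The mean of both responses asked what ibrutinib changed in the cell types on average. EGR2 fell from 3.11 ± 0.734 to 0.182 ± 0.107 CPM (SD, n = 3) in atrial and from 5.38 ± 0.990 to 1.65 ± 0.183 in ventricular cells (mean log2 change -2.90 ± 0.21, SE). The skeletal actin gene ACTA1 (-2.27 ± 0.21), NPPB (-2.58 ± 0.28) and ETV4 (-2.17 ± 0.13) fell too. ECM2 (1.52 ± 0.30), P2RY14 (1.34 ± 0.16), ART3 (1.27 ± 0.15), CRABP1 (1.26 ± 0.14), OGN (1.249 ± 0.17), LRRN3 (1.19 ± 0.08), PCDHGB1 (1.15 ± 0.32) and the apelin receptor ligand gene APELA (1.14 ± 0.25) rose, with adjusted p of 0.00867 or lower. Of these, ECM2, PCDHGB1 and APELA were scarce in atrial DMSO, at 0.255 ± 0.116, 0.140 ± 0.0714 and 0.180 ± 0.0951 CPM. In ventricular cells PCDHGB1 (0.17, adjusted p = 0.707) and APELA (0.19, adjusted p = 0.573) missed the threshold, as did CRABP1 (0.14, adjusted p = 0.426) and ECM2 (0.87, adjusted p = 0.0621). In all 4405 genes changed, 1928 higher and 2477 lower, of which 42 and 91 changed at least 2-fold. SELE, BMP10, MYBPC2 and CCL4L2 passed as well, but at least 1 group held almost no counts of each. SELE was at 0 in atrial ibrutinib, and MYBPC2 had 14 counts in atrial DMSO and 1 in atrial ibrutinib (ratio 14.4, exact 95% counting interval 2.19 to 607) and CCL4L2 17 and 1 (ratio 17.4, interval 2.73 to 729). BMP10 came to -0.77 in ventricular cells (adjusted p = 0.563), and its call for the mean was lost without ventricular DMSO replicate 1 (-1.84, adjusted p = 0.0523).

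Lists with more genes that fell than rose on average were ERK feedback (19 of 21 fell and 0 rose, 20 and 0 adjusted over the list alone), with SPRY4 at -1.90, ETV5 at -1.76 and DUSP6 at -1.68 (adjusted p = 0.0649 with an estimated correlation), and immediate early genes (18 of 20 fell and 0 rose, 19 and 0 adjusted over the list alone), with DUSP1 at -0.96 and IER2 at -0.60 (adjusted p = 0.119 with an estimated correlation). Of 24 cholesterol synthesis genes 21 fell and 0 rose (23 and 0 adjusted over the list alone, adjusted p = 0.119 with an estimated correlation). Of 12 fatty acid synthesis genes 10 fell and 0 rose (10 and 0 adjusted over the list alone). SCD stood at -0.65 and FASN at -0.63 (adjusted p = 0.0649 with an estimated correlation). Of 12 stress and natriuretic genes 10 fell and 1 rose (11 and 1 adjusted over the list alone). CTGF stood at -0.98 and THBS1 at -0.79 (adjusted p = 0.0649 with an estimated correlation). In ventricular cells CTGF came to 0.015 (edgeR adjusted p = 0.905). The list missed the threshold there, with 5 fallen and 1 risen (limma camera with the preset correlation, adjusted p = 0.272). Of 32 proliferation genes 14 rose and 5 fell (15 and 5 adjusted over the list alone). KIF20A stood at 0.46 and CENPF at 0.39 (adjusted p = 0.648 with an estimated correlation). Of 12 nodal markers 5 rose and 0 fell (5 and 0 adjusted over the list alone). RGS6 stood at 0.67 (adjusted p = 0.235 with an estimated correlation). With library totals 19 proliferation genes rose and 1 fell, and 8 nodal markers rose and 0 fell.

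In all 20 lists passed for the mean with the preset correlation, 2 higher and 18 lower. The others that were lower were YAP, ATF4, NF-kB, retinoic acid and aryl hydrocarbon receptor targets, glycolysis and hypoxia, oxidative phosphorylation, ribosomal protein, unfolded protein response, heat shock, circadian, smooth muscle and endothelial genes, with 0 of the 20 past the threshold with an estimated correlation (limma camera, adjusted p from 0.12 to 0.794 for these others), where 8 had an unadjusted p under 0.05. Of these, 6 calls ended when 1 library was left out. They were ribosomal proteins (lost without atrial DMSO replicate 3, atrial ibrutinib replicates 1 or 2 or ventricular ibrutinib replicate 3, adjusted p 0.0563 to 0.138), the unfolded protein response (without atrial ibrutinib replicate 3, 0.0506) and aryl hydrocarbon receptor targets (without atrial DMSO replicate 1 or ventricular ibrutinib replicate 3, 0.0515 to 0.0545). Heat shock genes lost theirs without atrial DMSO replicates 1 or 3, atrial ibrutinib replicates 1 or 2, ventricular DMSO replicate 2 or ventricular ibrutinib replicate 3 (adjusted p 0.0505 to 0.115), circadian genes without atrial DMSO replicate 2, atrial ibrutinib replicate 1 or ventricular DMSO replicates 1 or 3 (0.0515 to 0.0845), and endothelial genes without atrial DMSO replicates 1 or 3, atrial ibrutinib replicate 2, ventricular DMSO replicate 2 or ventricular ibrutinib replicate 3 (0.0516 to 0.102). With a filter at 1 CPM the heat shock and endothelial calls were lost as well (adjusted p 0.055 and 0.0865). The ribosomal protein median went from -0.054 to 0.024 when library totals replaced TMM. The oxidative phosphorylation median went from -0.079 to -0.0013 and the circadian median from -0.090 to -0.012. Those of retinoic acid targets, YAP targets, smooth muscle and endothelial genes went from -0.127, -0.18, -0.145 and -0.20 to -0.048, -0.10, -0.067 and -0.12. Unfolded protein response genes went from 0 higher and 9 lower to 3 and 2, and heat shock genes from 0 and 5 to 3 and 3. Library totals also gave 4010 higher and 1429 lower genes in place of 1928 and 2477. Some lists lower on average moved in opposite directions by cell type. Glycolysis and hypoxia had 9 higher and 2 lower genes in atrial and 0 and 24 in ventricular cells. Heat shock had 0 and 12 in atrial and 5 and 0 in ventricular cells. ERBB4 (0.37), ERBB2 (0.15) and IRX4 (0.51) rose on average and NPPA fell by 0.39, although ERBB2 and NPPA missed the threshold in ventricular cells. KCNA5 fell by 0.34, a call lost without ventricular DMSO replicate 3 (-0.25). MYL2, NR2F2, TNNT2, BTK, TEC, CSK, EGFR, KCNJ3, KCNJ2, CACNA1C, RYR2 and ATP2A2 missed the threshold, with adjusted p from 0.0608 to 0.911.

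The last comparison tested which genes responded differently in the cell types, as the atrial minus the ventricular log2 change. Of 5888 genes that differed, 1174 were called in opposite directions and 143 in the same direction, while 2567 were called in atrial and 1479 in ventricular cells alone. The aldolase gene ALDOC rose by 0.61 in atrial and fell by 0.98 in ventricular cells (difference 1.59 ± 0.09, SE), DUOX2 rose by 1.253 and fell by 0.64 (1.89 ± 0.11), and the sodium-glucose transporter gene SLC5A1 fell by 0.51 and rose by 0.99 (-1.50 ± 0.09). CMTM5 (-1.79 ± 0.09) and NUAK1 (-1.77 ± 0.09) also fell in atrial and rose in ventricular cells, and IGFBP2 fell by 1.42 in ventricular cells and rose by 0.30 in atrial cells (1.72 ± 0.10). DGKI and CTGF fell by 1.97 each in atrial cells, with ventricular changes of -0.015 and 0.015 that missed the threshold (differences -1.95 ± 0.09 and -1.99 ± 0.10). Of the 5888 genes, 2905 had a higher and 2983 a lower value in atrial cells, or 4364 and 1643 with library totals, which moved the median of all genes by 0.133. These 8 genes had the smallest p of the comparison, with adjusted p of 1.85e-12 or lower.

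Among lists, all but 3 of 24 glycolysis and hypoxia genes had a more positive response in atrial cells (21 higher and 0 lower, 21 and 0 adjusted over the list alone), with CA9 at 3.27 ± 0.38 and GAPDH at 0.77 ± 0.11 (adjusted p = 0.425 with an estimated correlation). So did NF-kB targets (13 of 17 higher and 0 lower, 14 and 0 adjusted over the list alone), with NFKBIA at 0.89 and ICAM1 at 1.69 (adjusted p = 0.286 with an estimated correlation), and fibroblast matrix genes (15 of 21 higher and 0 lower, 17 and 0 adjusted over the list alone), with LOX at 1.05 (adjusted p = 0.425 with an estimated correlation). Of 18 interferon-stimulated genes 11 were higher and 0 lower (14 and 0 adjusted over the list alone). BST2 stood at 0.97 and IFIT3 at 2.67 (adjusted p = 0.286 with an estimated correlation). Sarcomere genes had a more negative response in atrial cells (20 of 27 lower and 1 higher, 20 and 1 adjusted over the list alone), with UNC45B at -1.002 and MYH7 at -1.80 (adjusted p = 0.313 with an estimated correlation), as did ERK feedback genes (15 of 21 lower and 0 higher, 15 and 1 adjusted over the list alone), with SPRY4 at -2.62 and ETV5 at -2.45 (adjusted p = 0.286 with an estimated correlation). Heat shock genes were lower in 13 of 14 cases (13 adjusted over the list alone), with HSPH1 at -1.26 (adjusted p = 0.286 with an estimated correlation), and in 8 with library totals (median -0.30 in place of -0.43). In all 14 lists passed with the preset correlation and 0 with an estimated one (limma camera), where 6 had an unadjusted p under 0.05.

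Of the genes named in advance, NPPA (-0.75), MYL2 (-0.85), TNNT2 (-0.38), KCNJ3 (-0.64), CACNA1C (-0.44) and ATP2A2 (-0.51) had a more negative response in atrial cells and EGFR (0.67) a more positive one. ERBB4 stood at -0.26, a call lost with library totals (-0.13), without atrial DMSO replicate 1 (-0.21) and without ventricular ibrutinib replicate 3 (-0.24). KCNA5 stood at 0.51 (adjusted p = 0.0469), a call lost without any of 9 of the 12 libraries (0.32 to 0.54), among them ventricular DMSO replicate 3 (0.32, adjusted p = 0.261), and with RLE size factors (0.49, adjusted p = 0.0524). NR2F2, IRX4, BTK, TEC, CSK, ERBB2, KCNJ2 and RYR2 missed the threshold, with adjusted p from 0.118 to 0.927.

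Over all genes the responses of the cell types were nearly uncorrelated. Pearson's r of the log2 changes was -0.0647 and Spearman's rho -0.0981 across 18021 genes, which are not independent replicates. Of 1896 genes called in both cell types, 266 rose in both and 456 fell in both, while 594 rose in atrial and fell in ventricular cells and 580 did the reverse. Independent lists of the same sizes would share 279, 475, 401 and 331 genes. All 1174 genes called in opposite directions also passed the test of the difference. This was nearly fixed in advance, since opposite changes add up in the difference and come from the same fit. The genes that fell in both cell types included SPRY4, ETV5, DUSP6 and EGR2, and ERBB4, IRX4 and KCNIP2 rose in both.

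Each response ran against the difference between the cell types. Of 4991 genes called both in the atrial response and between atrial and ventricular DMSO, 4309 (86.3%) moved towards the ventricular level. Independent lists would share 4117.9 genes, of which 49.8% would move that way. In ventricular-like cells 3358 of 3945 (85.1%) moved towards the atrial level, against 50.3% of the 3269.9 that independent lists would share. The response and the baseline difference share their DMSO libraries, so part of this arises by chance. The covariance across genes was -0.19 in atrial cells, against -0.0197 (range -0.0251 to -0.0143) in 100 simulations of unchanged groups, and 0.175 against 0.0142 (range 0.0116 to 0.0187) in ventricular cells. Pearson's r was -0.417 (simulated -0.0995) and 0.462 (simulated 0.0852). The simulations held only the spread between replicates, and 3 control libraries per cell type could not be split into parts of 2 or more. Part or all of the excess may therefore come from the shared controls. The planned marker lists showed no clear shift. Of 18 atrial markers 3 rose and 5 fell in atrial and 2 rose and 5 fell in ventricular cells. Of 13 ventricular markers 6 rose and 6 fell in atrial and 5 rose and 3 fell in ventricular cells. These lists missed the threshold (limma camera, adjusted p from 0.239 to 0.959).

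**Figure D4:**
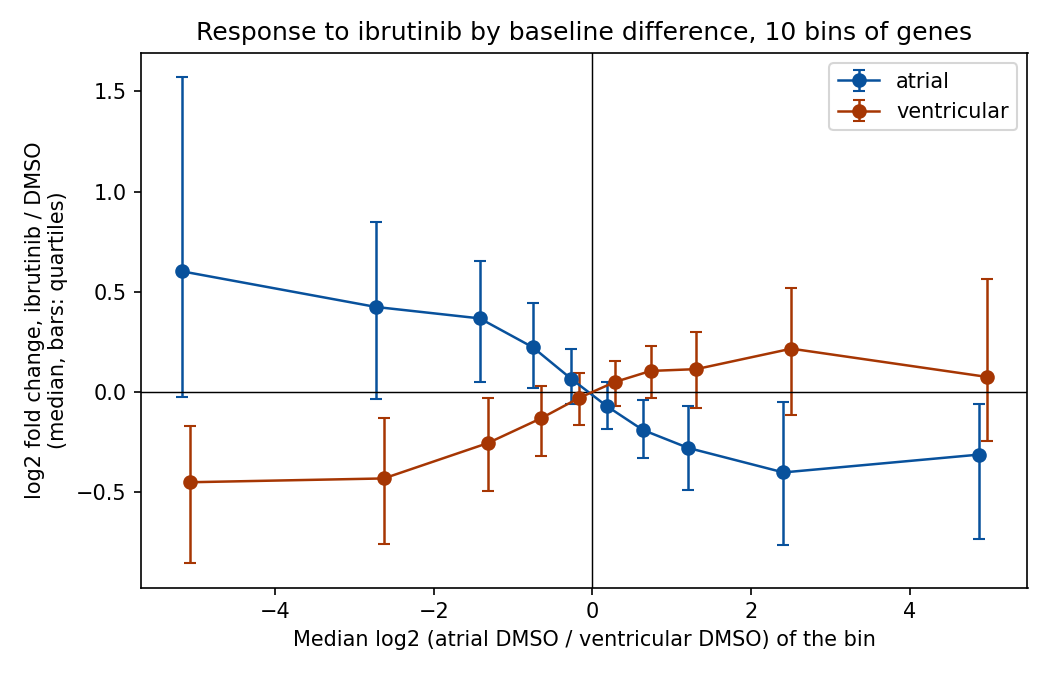
Median log2 fold change under ibrutinib (y axis, whiskers at the quartiles) for 10 bins of genes ordered by their log2 difference between atrial and ventricular DMSO (x axis, bin median), with the atrial and ventricular points offset sideways for legibility. Genes with a baseline difference between -4 and -2 have a median response of 0.42 in atrial and -0.43 in ventricular cells, and those between 2 and 4 have -0.40 and 0.22.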

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

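The tests of shared DMSO libraries, RNA of the other cell type, a changed mix of cell types, a loss of squamous-type cells and abundant genes were chosen only after the results were seen. The results here are those in which the response to ibrutinib differed between the cell types by the test of the difference itself, given as the atrial minus the ventricular log2 change. In all 5888 genes differed. Of 100 splits drawn from the 200 possible within cell types, the real one gave the most genes (5888 against 4405 in the next). That next split exchanges the drug labels of 1 cell type only, which turns the difference into the mean. The splits regroup drug and vehicle libraries, so they test for no drug effect at all, not for an equal response in both cell types. They therefore cannot exclude chance for the difference. For the 14 lists past the threshold chance is not excluded, since 17 of the 100 splits gave as many, with 20 in the highest. With an estimated correlation 0 of the 14 passed (limma camera, lowest adjusted p = 0.286).

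The median difference was -0.607 for sarcomere, -1.05 for stress and natriuretic, -0.749 for ERK feedback, -0.463 for YAP target, -0.377 for cholesterol synthesis, -0.184 for oxidative phosphorylation, -0.432 for aryl hydrocarbon receptor target, -0.43 for heat shock and -0.818 for smooth muscle genes. It was 1.13 for glycolysis and hypoxia, 0.194 for ribosomal protein, 0.816 for interferon, 0.885 for NF-kB target and 0.644 for fibroblast matrix genes. None of these 14 lists passed with an estimated correlation (adjusted p 0.286 to 0.651). With library totals the median was -0.245 for cholesterol synthesis, -0.0533 for oxidative phosphorylation (5 genes lower in place of 11) and 0.324 for ribosomal protein genes (30 higher in place of 10). The oxidative phosphorylation call was lost without atrial ibrutinib replicate 1 (adjusted p = 0.0524).

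Among single genes the difference was -1.95 for DGKI, -1.79 for CMTM5, -1.99 for CTGF, -1.77 for NUAK1, -1.50 for SLC5A1, 1.89 for DUOX2, 1.59 for ALDOC and 1.72 for IGFBP2. Of the genes named in every contrast it was -0.75 for NPPA, -0.85 for MYL2, -0.38 for TNNT2, 0.67 for EGFR, -0.26 for ERBB4, 0.51 for KCNA5, -0.64 for KCNJ3, -0.44 for CACNA1C and -0.51 for ATP2A2. The ERBB4 call was lost without atrial DMSO replicate 1 (-0.21) or ventricular ibrutinib replicate 3 (-0.24), and that of KCNA5 without any of 9 libraries, with 0.32 without ventricular DMSO replicate 3. Muscle and stress list members were UNC45B at -1.002, SMPX at -0.86, XIRP1 at -1.22, MYH11 at -1.18 and LMOD1 at -1.10. Signalling and lipid list members were SPRY4 at -2.62, ETV5 at -2.45, AMOTL2 at -1.004, HMGCS1 at -0.66, STARD4 at -0.65, CYP1B1 at -1.84 and TIPARP at -0.48. Heat shock and mitochondrial members were HSPH1 at -1.26, HSPA8 at -0.95, NDUFS1 at -0.54 and CYCS at -0.63. More positive in atrial cells were P4HA1 at 1.19, CA9 at 3.27, RPL15 at 0.40, RPL13 at 0.35, BST2 at 0.97, IFIH1 at 1.88, NFKBIA at 0.89, TNFAIP2 at 1.46, COL6A2 at 1.13 and COL6A1 at 0.71.

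Each response ran against the difference between the cell types, with a covariance over genes of -0.19 in atrial and 0.175 in ventricular cultures. Shared DMSO libraries alone gave -0.0197 and 0.0142 in simulations that held only the spread between replicates. An error common to all DMSO libraries of a cell type was not simulated. Shared controls therefore cannot be excluded as the whole cause. RNA of the other cell type would raise that type's own genes together, but their median gain was a share of 0.00848 (upper quartile 0.0212) in atrial and 0.00118 (0.00748) in ventricular cultures, where 0.5 of the share fitted to all genes is 0.0215 and 0.0324, which argues against it, by a narrow margin in atrial cultures. The highest and lowest lists of other cell types differed by 0.854 ± 0.165 (SE over genes) in atrial and 0.453 ± 0.107 in ventricular cultures. This SE takes the genes of a list as independent, and the lists compared were the extremes. In ventricular cultures both were chosen after the data were examined. A changed mix of cell types, uniform or in 1 of these types, therefore stays open. A response of the cells to the drug may account for the pattern, as a hypothesis.

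Glycolysis and NF-kB genes fell in ventricular cultures (adjusted p = 0.307 and 0.2 with an estimated correlation). With a trend in gene length and abundance removed, their medians were -0.804 and -0.857, so the falls remained. The trend took only 3.53% of the variance of the fold changes, so its removal could move the medians little. Fewer squamous-type cells would need those cells to hold a median share of 1.27 of the glycolysis transcripts (bootstrap interval 1.01 to 2.14) and 1.48 of the NF-kB transcripts (0.882 to 2.57). This loss and a drug response cannot be told apart here, since the shares rest on a list chosen from these data and on the assumption that the squamous genes come from those cells alone.

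ERK feedback and cholesterol genes fell in atrial cultures (adjusted p = 0.1 and 0.162 with an estimated correlation). With the length and abundance trend removed the medians were -1.14 and -0.508. With library totals they were -0.999 and -0.422, and without the 20 most abundant genes -1.13 and -0.556. The falls thus remained under each change, but these tests could hardly have ended them. The trend took only 5.54% of the variance of the fold changes. The 10 most abundant genes took a smaller share of counts with ibrutinib (8.97% against 11.1%), which would raise other genes and not lower them. A drug response is a candidate explanation, untested by other means here.

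For the contrasts of 3 libraries against 3 only 10 splits exist, too few for a share under 0.05. The real split gave 5808 atrial, 4612 ventricular and 12777 DMSO genes against 0 in the highest other split of each, 1 of 10 splits in each case, and 16, 16 and 24 lists against 13, 13 and 23, with 0 lists past the threshold in each with an estimated correlation. For the mean response 2 of 100 splits gave at least 4405 genes, with 5888 in the highest. That highest split exchanges the labels of 1 cell type. These splits also test only for no drug effect at all, so a response in 1 cell type alone could pass them. The low share speaks against a chance division of these libraries in that sense only, not for an effect shared by both cell types. Chance between cultures cannot be excluded, since replicates may be technical. For lists with the preset correlation 1 of 100 splits gave 20, with 19 in the next and a median of 8 in the others. Regrouped labels passed nearly as many lists, so no conclusion is drawn from the list count. With an estimated correlation 0 of the 20 lists passed (lowest adjusted p = 0.0649).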

How the results depend on the processing

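The alternatives here were all chosen in advance, and no test was chosen only after the result was seen. Total counts of changed genes stayed within 1.5 times under every alternative run. In a fit of only the groups needed, 5018 atrial and 5547 ventricular genes changed, in place of 5808 and 4612. Which cell type had more changed genes thus depended on the fit. Higher ventricular genes alone went from 1892 to 1161 without ventricular DMSO replicate 3, and to 1217 and 1256 without ventricular ibrutinib replicates 1 and 2. With each library left out they ranged from 4594 to 6040 (atrial), 3157 to 4629 (ventricular), 3585 to 5111 (mean), 5041 to 6207 (difference of responses) and 12055 to 12293 (DMSO contrast). DESeq2 gave 5121, 3799, 3834, 5288 and 12079. Library totals gave 6711, 4602, 5439, 6007 and 13292, with 77.0%, 44.1%, 73.7%, 72.6% and 26.7% of calls higher in place of 45.8%, 41.0%, 43.8%, 49.3% and 48.2%. List counts fell from 16, 16, 20, 14 and 24 to 0 in each contrast with an estimated correlation (limma camera); the cause was not tested. The correlation of the responses ranged from -0.0984 to -0.0230 with libraries left out. Replicate numbers did not pair the samples: 0 of 18 same-numbered pairs had r over 0.1 (-0.0712 to 0.0773), and 3 of 12 libraries correlated best with their own number. With a replicate block the counts were 5754, 4556, 4355, 5825 and 12718 genes. Of the main calls, 5651, 4448, 4253, 5725 and 12663 genes kept theirs with the block. Among named genes and lists the block ended only the heat shock call for the mean (limma camera, adjusted p = 0.0508). Of 351 called named-gene results 327 kept their call in every setting and 24 lost it in some. With the preset correlation, lists were tested again only with a filter at 1 CPM, the replicate block and each library left out. In these settings 80 of 90 list calls kept theirs and 10 lost it in some. The list test was not run with library totals, RLE size factors, no count filter or a fit of only the groups needed. The 1 reversal was ERBB2, baseline, at -0.040 (adjusted p = 0.527) with library totals, which shift the median of all genes. In 6 settings a named gene had no value. At this depth the smallest simulated changes were called in 16.3% to 46.9% of genes.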

Other observations

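The squamous, thyroid and eye or pigment lists and the genes named here were chosen only after their values were seen, while the edgeR tests and the left-out libraries were planned. Ventricular DMSO cultures carried mRNA of epithelial lineages. Of 20 squamous genes 19 stood at 1 CPM or more there and 12 did in atrial DMSO. KRT19 stood at 882 ± 71.7 CPM (SD, n = 3) in ventricular DMSO and 51.5 ± 9.28 in atrial DMSO, and the hemidesmosome gene COL17A1 at 129 ± 8.67 and 5.78. Under ibrutinib KRT19 fell by 0.90 ± 0.19 (SE, edgeR adjusted p = 0.00959), COL17A1 by 0.91 ± 0.13 (adjusted p = 0.00038) and the desmosome gene PKP1 by 1.06 ± 0.10 (adjusted p = 1.29e-08) in ventricular cultures. KRT5 came to -0.71 ± 0.26 (adjusted p = 0.0811), short of the threshold, and the KRT17 call (-0.83) was lost without any of 5 of the 6 ventricular libraries (-0.88 to -0.77).

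Genes of thyroid and pigment cells were present in the same cultures. The thyroglobulin gene TG stood at 150 ± 15.2 CPM in ventricular DMSO and 1.80 in atrial DMSO, the thyroid factor gene FOXE1 at 48.3 ± 2.23 and PAX8 at 41.9 ± 2.86. Their log2 values under ibrutinib in ventricular cultures were -0.024 (TG, adjusted p = 0.881), 0.15 (FOXE1, adjusted p = 0.151) and -0.0094 (PAX8, adjusted p = 0.954), and the pigment gene TYRP1 came to 0.011 (adjusted p = 0.951). Of the lists, 10 of 20 squamous genes fell and 0 rose in ventricular cultures, 5 of 11 thyroid genes fell and 0 rose, and 3 of 15 eye and pigment genes fell and 1 rose. In atrial cultures 2 squamous genes fell and 0 rose, 3 thyroid genes rose and 0 fell, and 2 eye and pigment genes rose and 1 fell.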
